A study of Mus musculus with 39 samples.

How the data were processed

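RNA from sorted donor-derived bone marrow cells of 39 mice was measured on 1-colour Affymetrix mouse gene arrays, 1 array per mouse. The values used here are the authors' deposited log2 expression values for 27037 probe sets. Per the submitters' notes, these were made with RMA and Partek 6.0. RMA sets all arrays of a study to one distribution of probe intensities and then summarises each probe set on the log2 scale, so a difference of 1 is a 2-fold difference. The authors' filters, batch steps and background setting are not given in the sources used here. The medians of the deposited columns lay between 5.38 and 5.76 and their SDs between 1.43 and 2.08, so the arrays still differed in spread after the authors' normalization.

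Arm, passage and replicate number came from each array's title. There were 13 groups of 3 mice. The labels number the mice within each group and do not say which donor seeded which recipient, so p-values measure the spread between these recipient mice. Pairwise correlations between arrays of a group ran from 0.885 to 0.992, and 0 pairs of arrays held identical values.

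Gene symbols came from the platform annotation, which gave 1 symbol for 23521 probe sets, several for 1814 and none for 1702. Probe sets with several symbols or none were left out of the gene tests. The probe set annotated to both Mir126a and Egfl7 is therefore described as a probe set and not as either gene. For 1082 genes with more than 1 probe set, the probe set with the highest mean over all arrays was kept, which left 22180 genes.

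All 39 arrays entered 1 linear model with 13 group means in limma 3.58.1 under R 4.3.3, with 26 residual degrees of freedom, and the empirical Bayes test was applied to each difference. Adjusted p-values are Benjamini-Hochberg values over the 22180 genes of a comparison, and a gene passed at an adjusted p under 0.05 with no minimum fold. A ± after a log2 difference is its standard error from this model. The 19 comparisons were each arm at passage 1 against the normal controls, each miR-126 arm against AE9a at each passage and averaged over the 4 passages with equal weight, the miR-126 arms against each other, passage 4 against passage 1 in each arm, and the change of each miR-126 effect between passages 1 and 4. Median standard errors were 0.222 for 3 mice against 3, 0.111 for the averages and 0.314 for the changes of an effect.

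Before the data were examined, 23 gene lists were fixed from general knowledge of haematopoiesis and of miR-126, as were the design, the rule for named genes and all alternatives but 3. They cover the miR-126 locus, reported miR-126 targets, fusion and runt genes, t(8;21) markers, stem, granule and mature blood cell genes, stroma, cell cycle, interferon, MYC and ribosome biogenesis, immediate early, ERK feedback, p53, sex-linked and housekeeping genes. Of 438 listed symbols 389 were measured, and 0 of these needed an older symbol. Some genes stand on more than 1 list, Errfi1 and Spred1 among them. Lists were tested with camera, which asks whether a list's genes shifted more than other genes, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists of a comparison; the test was repeated with the correlation estimated from the residuals, which is far stricter here. A list p-value is this adjusted camera p throughout. Genes of a list were also adjusted over the list alone.

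The rule for named genes took the 8 largest rises and 8 largest falls among genes that passed, for each comparison with normal controls where every mouse of one group lay above every mouse of the other, and for each average where the passage means differed in the same direction at all 4 passages. Single passages, comparisons of passage 4 with passage 1 and changes of an effect gave 4 of each, with no condition on overlap. Symbols of predicted genes, small RNAs, odorant and vomeronasal receptors and ribosomal pseudogenes were passed over. Egfl7, Runx1t1, Runx1, Errfi1, Spred1 and Zzef1 were named whatever their values, and each list gave up to 4 members with the smallest adjusted p.

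The alternatives fixed beforehand were a fit on the compared groups alone, the replicate number as a block, a trended and robust variance prior, a filter on dim genes, all probe sets, array weights, cyclic loess, a 2-fold minimum, passage as the unit, and leaving out each array or passage. Chosen after seeing the data were leaving out the arrays with an SD under 1.8, quantile normalization of the probe sets, and the spread of each array as a covariate.

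The fits were tested on simulated data with 200 changed genes among 22180 and the real residual variances. For AE9a against normal controls at 3 mice each, 11, 35, 48 and 50 of 50 genes changed 1.5-, 2-, 4- and 8-fold were recovered. Of unchanged genes 9 passed. For the averaged effect of added miR-126 the numbers were 33, 47, 50 and 50 of 50 with 14 unchanged genes, and for the change of the knockout effect between passages 3, 24, 45 and 48 of 50 with 6 unchanged genes. A list shifted 2-fold was called in each of 3 comparisons, and 0 of 10 unshifted lists were. Genes were simulated without correlation, so this cannot check the preset one. The number the test asks for at 8-fold, 45 of 50, was set after the 48 of 50 had been seen.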

Results

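The series profiled leukaemias driven by AE9a, a truncated splice form of the AML1-ETO fusion of t(8;21) acute myeloid leukaemia, in which the microRNA miR-126 was left alone, added or knocked out. Cells of each arm were passaged through recipient mice 4 times, and donor-derived cells were sorted from the marrow of sick recipients by their CD45 form before RNA was taken. Each arm had 3 mice at each passage (36 leukaemia arrays), and 3 mice of the first passage served as normal controls. Comparisons ask what the fusion did against normal marrow, what gain and loss of miR-126 changed, and how this differed between early and late passages. The number of arrays limits the precision.

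Arrays differed in spread. The SD of the log2 values over probe sets was 1.87 to 2.08 in the normal controls, 1.86 to 2.06 in AE9a, 1.78 to 2.04 in the knockout arm and 1.43 to 2.03 in the arm with added miR-126. Of the 8 arrays below 1.8, 7 belonged to the 9 arrays with added miR-126 at passages 2 to 4. They were replicates 1 and 2 of passages 2 and 4 and all 3 of passage 3. The other was replicate 3 of the knockout at passage 2 (1.78). Each difference below that involves added miR-126 at passages 2 to 4 moved together with this spread. Without the arrays of low spread, averages with added miR-126 run over passages 1, 2 and 4, with 1 of its arrays at each of passages 2 and 4.

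**Figure D1:**
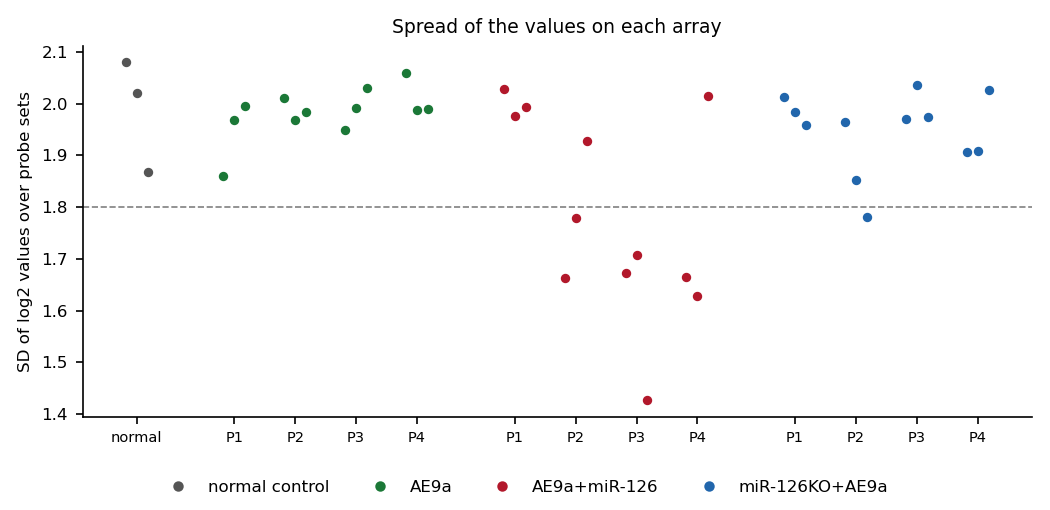
The y axis gives the SD of the log2 values over 27037 probe sets for each of the 39 arrays, by arm and passage, with 1 point per array and a dashed line at 1.8. The 8 arrays under the line are 7 with added miR-126 at passages 2 to 4, as low as 1.43, and 1 knockout array of passage 2.

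The probe set annotated to both Mir126a and its host gene Egfl7 was checked in each group first, on the log2 scale. With added miR-126 it read 8.31 ± 0.16 (SD, n = 3) at passage 1, 9.52 ± 1.84 at passage 2, 6.76 ± 0.79 at passage 3 and 7.28 ± 1.14 at passage 4, against 2.82, 2.87, 3.01 and 2.86 in AE9a. All 12 arrays with added miR-126 (5.90 to 11.6) lay above all 12 of AE9a (2.76 to 3.04), with adjusted p = 1.08e-14 in limma over the 4 passages. In the knockout arm it read 2.77 to 3.15. AE9a itself lay close to the lowest values on the arrays, as did the normal controls at 3.30 ± 0.51, so no fold is given, and this probe set shows the added miR-126 and cannot check the knockout. Egfl7 measured by its own probe set differed from AE9a by 0.09 ± 0.11 in both arms (adjusted p = 0.457 with added miR-126 and 0.762 in the knockout).

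Runx1t1 is the mouse counterpart of the fusion partner ETO, and whether its probes detect the transgene is not given in the sources used here. Over all passages it read 6.09 ± 0.26 (SD, n = 12) in AE9a, 6.29 ± 0.27 with added miR-126 and 5.89 ± 0.43 in the knockout, against 5.34 ± 0.23 in the 3 normal controls.

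**Figure D2:**
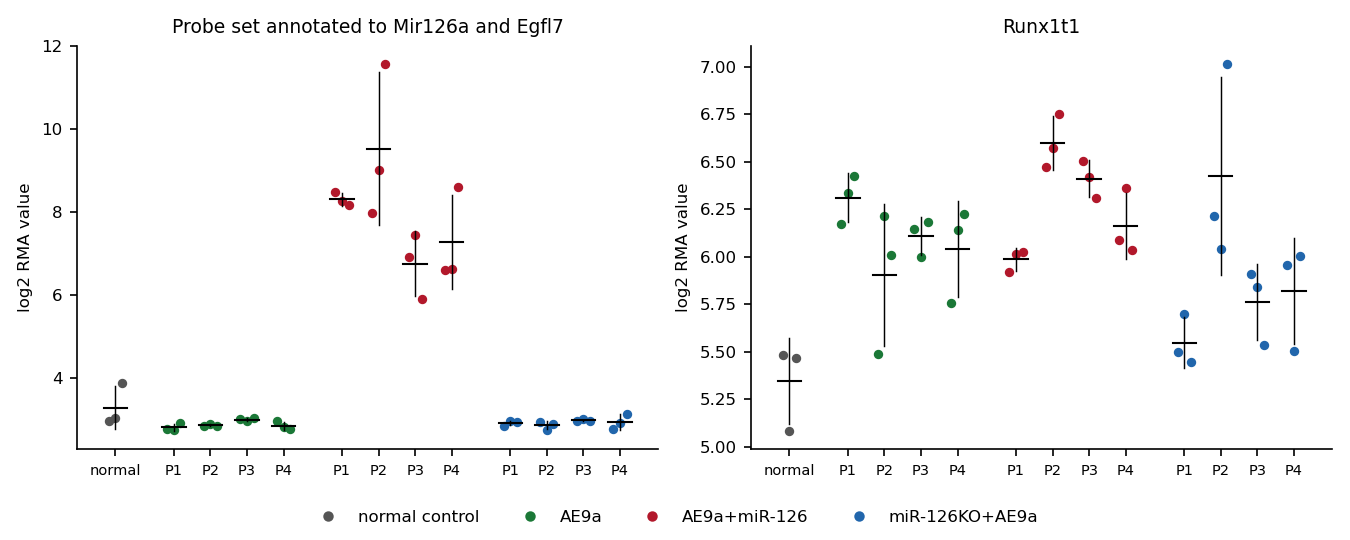
The panels show log2 values of the probe set annotated to Mir126a and Egfl7 and of Runx1t1 for each array by arm and passage, with points for arrays and lines for mean ± SD (n = 3). The probe set reads 5.90 to 11.6 in every array with added miR-126 and no higher than 3.88 in the others, and Runx1t1 averages 6.09 in AE9a against 5.34 in the normal controls.

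AE9a leukaemia at passage 1 was first set against normal marrow. The genes that rose furthest were Plet1 (5.86 ± 0.37 on the log2 scale, 58-fold, n = 3 and 3, adjusted p = 8.43e-12), Il1a (5.57 ± 0.83), which encodes the cytokine interleukin 1 alpha, Serpinb8 (4.41 ± 0.47) and Acod1 (3.82 ± 0.83), the enzyme that makes itaconate in macrophages. Errfi1, an inhibitor of EGF receptor signalling and a reported miR-126 target, rose by 3.52 ± 0.52 (11.4-fold). The deepest falls were in Car1 (-5.09 ± 0.69, 34-fold), a carbonic anhydrase of red cells, Far2 (-3.89 ± 0.49), Ctse (-3.83 ± 0.51) and Mcpt8 (-3.51 ± 0.50), a basophil protease. Runx1t1 rose by 0.97 ± 0.20 (adjusted p = 0.00201), while Runx1 (0.57, adjusted p = 0.15), Spred1 (1.00, adjusted p = 0.0876) and Zzef1 (0.31, adjusted p = 0.46) did not pass. In limma 1967 genes passed, 715 higher and 1252 lower (1741 and 1881 with the spread as a covariate).

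Genes of the red cell, basophil and B cell lineages fell in AE9a. Of 18 erythroid genes 14 fell (16 adjusted over the list alone), with a median of -1.82, and the list passed (adjusted p = 2.93e-17, and adjusted p = 0.0361 with estimated correlation); examples are Aqp1 (-2.91) and Slc4a1 (-2.00). Of 15 mast cell, basophil and eosinophil genes 8 fell (10 adjusted over the list alone), among them Prss34 (-3.19) and Epx (-1.99), with list adjusted p = 6.87e-11 and adjusted p = 0.0029 with estimated correlation. Of 18 B cell genes 9 fell (10 adjusted over the list alone), including Cd22 (-2.07) and Spib (-2.62), with list adjusted p = 1.61e-10 and adjusted p = 0.0353 with estimated correlation.

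Further lists passed in AE9a with the preset correlation and were lost with an estimated one. Primary granule genes fell as a list (4 of 14 fell, 6 adjusted over the list alone, Prss57 -2.51, adjusted p = 0.154 with estimated correlation). Stem and progenitor genes fell (6 of 28 fell, 7 adjusted over the list alone, where 3 also rose, Hoxa9 -1.02, adjusted p = 0.0865 with estimated correlation), and so did megakaryocyte genes (4 of 14, 7 adjusted over the list alone, Itgb3 -1.49, adjusted p = 0.0561 with estimated correlation). Cell cycle genes (7 of 30 fell, 13 adjusted over the list alone, Aurkb -1.63) and MYC and ribosome biogenesis genes (8 of 22, 10 adjusted over the list alone, Myc -1.40) gave adjusted p = 0.292 and adjusted p = 0.277 with estimated correlation. T and NK cell genes (3 of 20 fell, 8 adjusted over the list alone, Ncr1 -1.45), MHC class II and dendritic genes (4 of 15 by both adjustments, Ly6d -2.53), and monocyte and macrophage genes (7 of 24 fell and Cd14 rose by 3.28, 2 rose adjusted over the list alone) gave adjusted p = 0.277, 0.236 and 0.331 with estimated correlation. Interferon genes split, with 4 of 26 lower (Oas2 -2.08) and Cxcl10 higher by 3.04 (6 and 1 adjusted over the list alone), and the list's adjusted p = 0.0137 became adjusted p = 0.53 with estimated correlation.

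The lists that rose in AE9a had medians of 0.25, 0.21 and 0.15. Immediate early and inflammatory genes had 6 of 23 higher and 2 lower by both adjustments (Tnfaip3 2.45, Nfkbia 1.86, adjusted p = 0.507 with estimated correlation). Of 15 ERK feedback genes 4 rose (5 adjusted over the list alone, Dusp5 1.63, adjusted p = 0.134 with estimated correlation), and of 16 p53 targets 3 rose (5 adjusted over the list alone, Cdkn1a, the cell cycle inhibitor p21, by 2.62, adjusted p = 0.274 with estimated correlation). Mature neutrophil genes had 0 of 25 past the limma threshold (1 at an unadjusted p under 0.05, higher). Their median was -0.09 while the list test pointed up (adjusted p = 0.953). Stroma and endothelium genes had 2 of 18 lower by both adjustments (Cxcl12 -1.57), a median of 0.13 and a mean of 0.03, while the test pointed down (adjusted p = 0.978), and did not pass. Neither did t(8;21) markers (3 of 11 rose and 2 fell, 3 and 3 adjusted over the list alone, Jup 2.14, adjusted p = 0.199) or reported miR-126 targets (3 of 17 rose and 2 fell, 4 and 3 adjusted over the list alone, Tsc1 0.85, adjusted p = 0.512). Among 6 fusion and runt genes Runx1t1 rose and Cbfa2t3 fell by 1.19 (median -0.02, mean 0.01, adjusted p = 0.674). Kdm5d was the 1 lower gene of 4 sex-linked genes (-2.30, list adjusted p = 0.189), and Sdha fell by 1.19 among 9 housekeeping genes (median 0.04, mean -0.22, adjusted p = 0.382). The miR-126 locus list held 1 measured gene, Egfl7 (-0.27, adjusted p = 0.481), so no list test was made. Leaving out AE9a replicate 1, AE9a replicate 2 or normal replicate 1 gave 865, 1006 and 1177 genes. Cyclic loess gave 3021. The 3 controls are shared with the next comparisons.

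Leukaemia with added miR-126 was set against normal marrow at passage 1 too. Il1a rose by 6.73 ± 0.83 (106-fold, adjusted p = 2.22e-06), Plet1 by 5.71 ± 0.37, Mmp13, a collagenase, by 5.22 ± 0.72, and Errfi1 by 4.56 ± 0.52. Car1 (-5.32 ± 0.69), Car2 (-3.82 ± 0.80), Mcpt8 (-3.52 ± 0.50) and Rhag (-3.51 ± 0.71) fell. Runx1t1 (0.64 ± 0.20, adjusted p = 0.0347), Runx1 (0.77 ± 0.25, adjusted p = 0.0422) and Spred1 (1.96 ± 0.37, adjusted p = 0.000632), which restrains RAS signalling and is a reported miR-126 target, rose. In all, 2159 genes passed, 1011 higher and 1148 lower. Leaving out replicate 2 or 3 with added miR-126 gave 1354 and 1319.

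In this comparison 11 of 18 B cell genes fell (15 adjusted over the list alone, Ms4a1, which encodes CD20, by 2.55), with list adjusted p = 1.12e-14 and adjusted p = 0.00679 with estimated correlation. Erythroid genes (13 of 18 fell, 16 adjusted over the list alone), mast cell genes (9 of 15, 11 adjusted over the list alone) and megakaryocyte genes (5 of 14, 6 adjusted over the list alone, Clec1b -1.11) fell, with adjusted p = 0.0233, 0.00132 and 0.017 with estimated correlation. ERK feedback genes rose (4 of 15, 6 adjusted over the list alone, Dusp5 2.22, adjusted p = 0.00109, and adjusted p = 0.0445 with estimated correlation). Immediate early genes (8 of 23 rose and 1 fell, 10 and 1 adjusted over the list alone, Tnf 3.24, Tnfaip3 3.32) and p53 targets (5 of 16 rose by both adjustments, Cdkn1a 3.51, Mdm2 1.55) passed and were lost, with adjusted p = 0.158 and adjusted p = 0.103 with estimated correlation. For t(8;21) markers 4 of 11 rose and 2 fell by both adjustments, with Cav1 at 3.27, and the list's adjusted p = 0.0343 became adjusted p = 0.0784 with estimated correlation. Mature neutrophil genes had 0 of 25 past the limma threshold (1 higher and 6 lower at an unadjusted p under 0.05), a median of -0.68 and a list adjusted p = 0.0113 that became adjusted p = 0.599 with estimated correlation.

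Knockout leukaemia at passage 1 differed from normal marrow in genes of the interferon response and of neutrophils. Of 26 interferon genes 16 rose (22 adjusted over the list alone), with Cxcl10, a chemokine induced by interferon, at 5.05 ± 0.57 (33.1-fold, adjusted p = 3.54e-07), Ifit1 at 4.22, Mx2 at 3.16 and Usp18 at 2.93; the list passed (adjusted p = 1.28e-16, and adjusted p = 0.0406 with estimated correlation). Of 25 mature neutrophil genes 14 fell (16 adjusted over the list alone), with Ly6g at -4.17 ± 0.94 and Mmp9 at -3.77 ± 0.88, at list adjusted p = 4.51e-11 and adjusted p = 0.129 with estimated correlation. Mmp13 (5.61 ± 0.72, 48.7-fold), Il1a (5.46 ± 0.83), Dab2 (5.08 ± 0.81) and Errfi1 (4.40 ± 0.52) rose. Runx1 rose by 1.08 ± 0.25 and Spred1 by 2.35 ± 0.37, Egfl7 fell by 0.70 (adjusted p = 0.0302), and Runx1t1 was 0.20 ± 0.20 apart (adjusted p = 0.613). A total of 2393 genes passed, 1083 higher and 1310 lower, and 1518 and 1586 passed without knockout replicates 2 and 1.

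B cell genes had a median of -2.22 in the knockout at passage 1, with 13 of 18 lower (14 adjusted over the list alone, Spib -3.65 ± 0.39, Cd22 -3.03, adjusted p = 0.00313 with estimated correlation). Primary granule genes fell (9 of 14, 10 adjusted over the list alone, Nkg7 -3.06, adjusted p = 0.039 with estimated correlation). Mast cell genes fell (7 of 15, 8 adjusted over the list alone, Mcpt8 -4.15, adjusted p = 0.00313 with estimated correlation). Among 28 stem and progenitor genes 9 fell, with Cd34 at -2.38, and Procr rose by 1.66 (11 and 1 adjusted over the list alone, adjusted p = 0.035 with estimated correlation). Megakaryocyte genes fell in 5 of 14 (6 adjusted over the list alone, where 1 rose, Itgb3 -2.20, adjusted p = 0.039 with estimated correlation). Of 20 T and NK cell genes 11 fell (13 adjusted over the list alone, where 2 rose, Thy1 -1.26, adjusted p = 0.115 with estimated correlation). Erythroid genes had 4 of 18 lower by both adjustments (Aqp1 -2.97, adjusted p = 1.5e-05, and adjusted p = 0.211 with estimated correlation).

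Of 3745 genes that passed in at least 1 arm at passage 1, 337 were higher than normal in all 3 arms and 559 lower. AE9a and the arm with added miR-126 shared 469 higher and 783 lower genes, against 32.6 and 64.8 for independent lists of those sizes, with 0 in opposite directions. AE9a and the knockout shared 378 and 669 (34.9 and 73.9 independent) with 3 opposite, and the arms with added and deleted miR-126 shared 616 and 752 (49.4 and 67.8) with 0 opposite. Correlations of the log2 differences across genes were 0.840, 0.712 and 0.816 in that order. Simulated unchanged groups against the same controls gave means of 0.465, 0.457 and 0.456 and highest values of 0.870, 0.856 and 0.846, above those observed. Covariances were 0.0336, 0.0331 and 0.0333 against 0.255, 0.236 and 0.278 observed, with differences of 0.222, 0.203 and 0.245. The 3 controls are too few to split, so part of the excess of shared calls can come from them. Genes are not independent replicates.

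Added miR-126 was compared with AE9a over the 4 passages together. Gria3, a glutamate receptor subunit, rose by 3.20 ± 0.24 (9.18-fold, n = 12 and 12, adjusted p = 8.3e-11), Dscam, a cell adhesion molecule of neurons, by 3.15 ± 0.27, Cd163, the haemoglobin scavenger receptor of macrophages, by 3.02 ± 0.33, and Myb, a transcription factor of blood progenitors, by 2.44 ± 0.20. The largest falls were in H2-Ab1 (-3.97 ± 0.34, 15.7-fold, adjusted p = 5.57e-10) and H2-Aa (-3.89 ± 0.31), the chains of an MHC class II molecule, Pla2g7 (-3.92 ± 0.31), Csta2 (-3.49 ± 0.35) and Cpa3 (-3.42 ± 0.37), a mast cell protease. Errfi1 (-0.85 ± 0.26) and Spred1 (-0.67 ± 0.18) fell in the average, while at passage 1, where no array had a low spread, they read 1.05 ± 0.52 and 0.96 ± 0.37 above AE9a (adjusted p = 0.96 and 0.757). Runx1 fell by 0.51 ± 0.12, read -0.26 without passage 3 and turned to 0.05 without all arrays of low spread, and Zzef1 fell by 0.35 ± 0.12 but turned to 0.11 after cyclic loess. Runx1t1 was 0.20 ± 0.10 apart (adjusted p = 0.0875). In limma 12211 genes passed, 6815 higher and 5396 lower, which is 55.1% of those tested, and 1302 of them differed 2-fold or more, 293 higher and 1009 lower. The total was 2813 with the spread as a covariate, 7872 after cyclic loess, 4204 without passage 3 and 982 without the arrays of low spread, passage 3 among them. With passage as the unit, each group of 3 mice as 1 value, 1 gene passed. Of 50 named genes that passed in this average 13 lost the call or turned with the spread as a covariate and 19 without the arrays of low spread, Spred1, Crk, Ptpn9, Tom1, Phlda1, Flt3 and Elane among the latter, and Errfi1 and Adam9 lost it after cyclic loess.

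Some mature cell lists fell with added miR-126. Of 25 mature neutrophil genes 24 fell by both adjustments, with a median of -1.92. Itgam, which encodes CD11b, fell by 2.57, Csf3r, the G-CSF receptor, by 1.92 and Il1r2 by 2.76 (list adjusted p = 2.07e-14, and adjusted p = 0.269 with estimated correlation). Of 24 monocyte and macrophage genes 16 fell by both adjustments, among them Vcan (-3.02), Fcgr1 (-2.40), Lyz2 (-1.56) and Adgre1 (-2.19) (adjusted p = 1.05e-05, and adjusted p = 0.269 with estimated correlation). MHC class II and dendritic genes had 7 of 15 lower by both adjustments (H2-Eb1 -2.53), with a median of -0.25 and adjusted p = 0.314 with estimated correlation. Genes of T and NK cells had 13 of 20 lower and 2 higher by both adjustments (Ccl5 -2.49, Cd3g -1.94, adjusted p = 0.314 with estimated correlation). Interferon genes had 19 of 26 lower and 2 higher by both adjustments (Ifitm3 -1.93, Zbp1 -1.59, adjusted p = 2.13e-06, and adjusted p = 0.314 with estimated correlation). Each of these falls went with the narrower spread of 7 arrays.

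Reported targets of miR-126 fell as well. Among them 10 of 17 were lower and 1 higher by both adjustments, including Crk (-1.02), Ptpn9 (-0.63), Tom1 (-1.18) and Adam9 (-0.85), with list adjusted p = 0.00438 and adjusted p = 0.269 with estimated correlation. ERK feedback genes had 8 of 15 lower by both adjustments (Phlda1 -1.17, and Spred2 -0.67, which turned to 0.11 without the arrays of low spread, adjusted p = 0.314 with estimated correlation). Immediate early genes had 11 of 23 lower and 3 higher by both adjustments (Il1b -2.92, Cxcl2 -2.46, adjusted p = 0.462 with estimated correlation), and the direction of this list's test turned after cyclic loess. Cell cycle genes had 18 of 30 lower by both adjustments (Rrm2 -0.99 and Ccna2 -0.90, which turned to 0.35 and 0.27 without the arrays of low spread), with a median of -0.52 that turned to 0.19 with the spread as a covariate, was -0.28 without passage 3 and turned to 0.37 without all arrays of low spread, and with adjusted p = 0.462 with estimated correlation.

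The lists that did not pass for added miR-126 held single genes that did. Among 28 stem and progenitor genes 7 rose and 7 fell by both adjustments (Flt3, a receptor of early progenitors, 1.48, Bcl11a -0.98, list adjusted p = 0.807). Among 18 B cell genes 3 rose, with Igll1, part of the surrogate light chain of B cell precursors, at 1.62, and 3 fell, with Cd79a at -1.57 (adjusted p = 0.435). Erythroid genes had 5 of 18 lower (3 adjusted over the list alone, Car2 -2.39, adjusted p = 0.0615), and mast cell genes 6 of 15 lower and 1 higher (Hdc -1.85, adjusted p = 0.105). Primary granule genes had 5 of 14 lower and 1 higher (Elane -1.52, adjusted p = 0.078) and megakaryocyte genes 3 of 14 lower and 2 higher (Thbs1 -3.34, adjusted p = 0.226). Stroma and endothelium genes (5 of 18 higher, 1 lower) and MYC and ribosome biogenesis genes (5 of 22 higher, 1 lower, 3 and 1 adjusted over the list alone) each gave adjusted p = 0.226. Of 16 p53 targets 8 fell and 2 rose (Mdm2 -0.91, Pmaip1 1.01, adjusted p = 0.0615). Of 11 t(8;21) markers 3 fell and 2 rose (Ubash3b -1.25, median 0.19, mean -0.08, adjusted p = 0.921). Of 6 fusion and runt genes 3 fell (Runx3 -0.51, adjusted p = 0.403), of 4 sex-linked genes 3 fell (Eif2s3y -1.91, adjusted p = 0.078) and of 9 housekeeping genes 4 fell (adjusted p = 0.078). Of the latter Hprt (-0.85) turned to 0.13 without the arrays of low spread and Ptprc (-0.47) to 0.00763 after cyclic loess. Where no second count is given here, adjusting over the list alone left the counts as they are.

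Passage by passage, added miR-126 went with 7 genes at passage 1, 1964 at passage 2, 11567 at passage 3 and 5488 at passage 4, while the number of low-spread arrays among the 3 was 0, 2, 3 and 2. Fitted on the compared groups alone the counts were 2, 917, 7261 and 1357, with 178 higher and 1179 lower at passage 4. At passage 1 the 6 higher genes were Tnfsf9 (2.98 ± 0.45, adjusted p = 0.00258), the microRNA gene Mir222 (2.59), Selp (2.06 ± 0.37), Cav1 (1.96 ± 0.31), Mt2 (1.62 ± 0.26) and Sele (0.96). Mir222 and Sele fall outside the naming rule and were chosen after their values were seen. The 1 lower gene was Fam167a (-1.16 ± 0.21, adjusted p = 0.0142), and 1165 genes had an unadjusted p under 0.05. Among lists that passed at passage 1 with the preset correlation were neutrophil genes (0 of 25 past the limma threshold and 2 lower at an unadjusted p under 0.05, median -0.67), MYC and ribosome biogenesis genes (0 of 22, 1 higher unadjusted, median 0.38) and immediate early genes (0 of 23, 6 higher unadjusted, 1 adjusted over the list alone, median 0.44). Each gave adjusted p = 0.453 with estimated correlation. The count at passage 1 was 57 without replicate 1 with added miR-126 and 3 without replicate 3, and after cyclic loess 4 of the 7 genes that passed were higher and 3 lower.

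At passage 2 with added miR-126 Myb rose by 3.36 ± 0.41 and Gria3 by 2.80 ± 0.49, and Pla2g7 (-4.99 ± 0.63, 31.7-fold), Ms4a4a (-4.77 ± 0.53), Vcan (-4.76 ± 0.54) and Ifi204 (-4.71 ± 0.55) fell. Monocyte and macrophage genes fell (9 of 24, 13 adjusted over the list alone, adjusted p = 0.256 with estimated correlation), as did interferon genes (10 of 26, 16 adjusted over the list alone, Oas2 -2.27, adjusted p = 0.403 with estimated correlation), while 1 of 25 neutrophil genes, Il1r2, fell (-2.52, list adjusted p = 0.251). Of the 1964 genes 705 were higher and 1259 lower. Leaving out each of the 6 arrays moved the total by more than 1.5-fold, from 396 without replicate 1 to 4694 without replicate 3, both with added miR-126.

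Passage 3 had the lowest spread and the most calls, 6056 higher and 5511 lower. The median over all genes was 0.117 there, and -0.019 after cyclic loess and -0.023 after quantile normalization, so a gene's log2 difference is to be read against that shift. Tmem178 (4.29 ± 0.53) and Gria3 (4.22 ± 0.49) rose, and Cpa3 (-6.10 ± 0.74, 68.4-fold), Fn1, which encodes fibronectin (-5.63 ± 0.59), and Thbs1 (-5.63 ± 0.51) fell. Neutrophil genes had 22 of 25 lower (23 adjusted over the list alone, median -2.57, Chil3 -3.55), and cell cycle genes 19 of 30 lower (20 adjusted over the list alone, Mki67 -1.54), each with adjusted p = 0.52 with estimated correlation. With the spread as a covariate the cell cycle median turned to 0.33. Leaving out replicate 3 with added miR-126 gave 7270 genes, cyclic loess 6767 and the spread as a covariate 1744.

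At passage 4 with added miR-126 Retnlg, a neutrophil granule gene, fell by 7.13 ± 0.62 (140-fold, adjusted p = 4.2e-09) and S100a8, a calprotectin subunit, by 4.84. In all 23 of 25 neutrophil genes fell (24 adjusted over the list alone, median -4.38, adjusted p = 2.39e-28, and adjusted p = 0.0686 with estimated correlation). Among T and NK cell genes 12 of 20 were lower and 1 higher (15 and 1 adjusted over the list alone), with Ccl5 at -5.38, Cd3g, a T cell receptor subunit, at -4.65 and Cd3e at -3.40, against AE9a arrays in which such genes had risen since passage 1 (adjusted p = 0.0686 with estimated correlation). ERK feedback genes had 6 of 15 lower (7 adjusted over the list alone, Dusp5 -1.40, adjusted p = 0.0686 with estimated correlation). Tmem178 (5.73 ± 0.53), Dscam (4.70 ± 0.54) and Cd163 (4.35 ± 0.67) rose. Of the 5488 genes 2825 were higher and 2663 lower. Without replicates 1, 2 and 3 with added miR-126 the totals were 2134, 2126 and 10765, and without replicate 1 of AE9a 3050. The median over all genes was 0.128 and became -0.003 after cyclic loess.

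**Figure D3:**
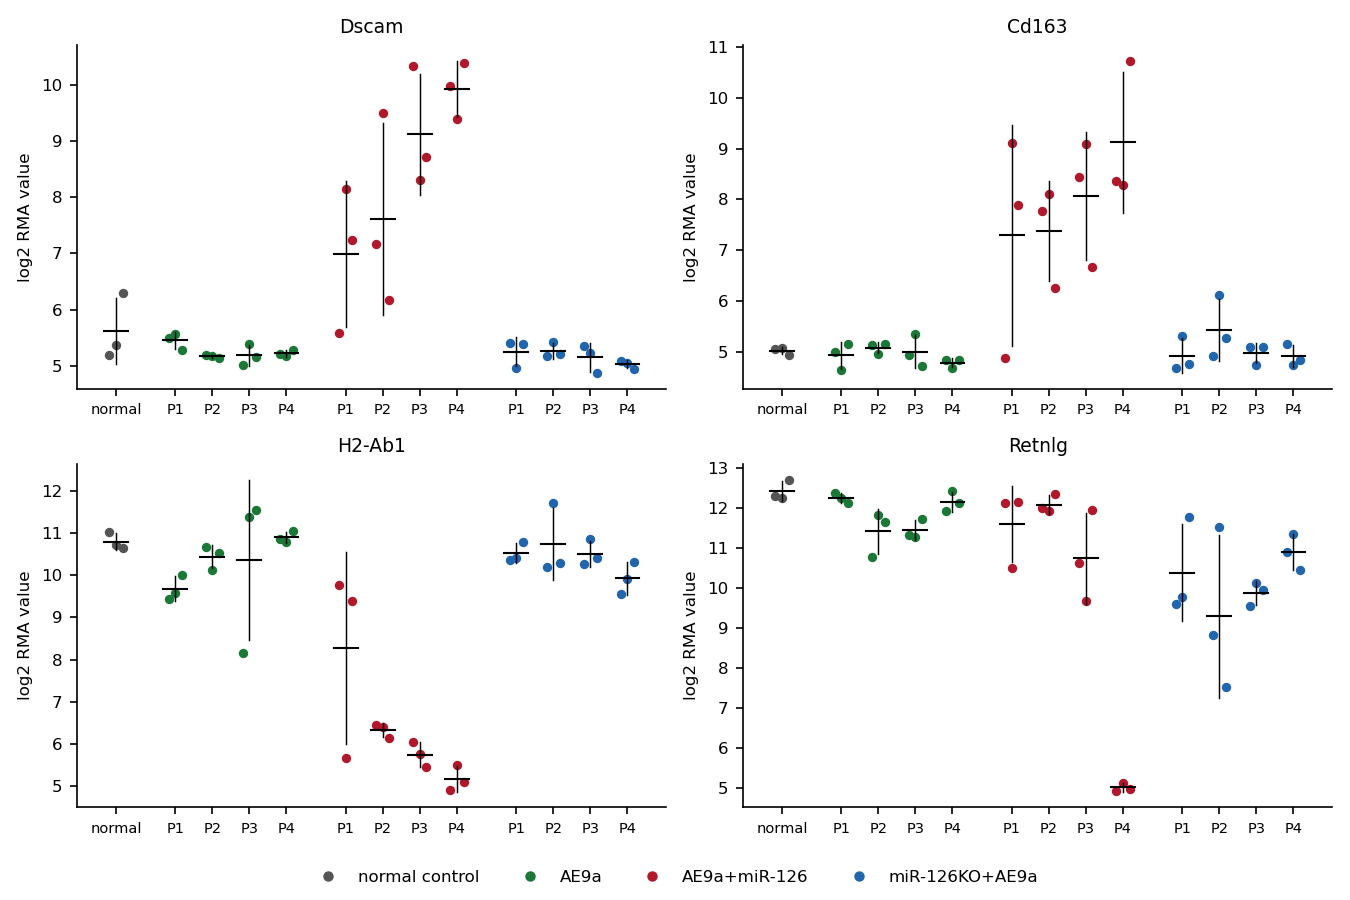
The panels show log2 expression of Dscam, Cd163, H2-Ab1 and Retnlg for each array by arm and passage, with points for arrays and bars for mean ± SD (n = 3). Against AE9a over 4 passages Dscam and Cd163 rose by 3.15 and 3.02 with added miR-126 and H2-Ab1 fell by 3.97, and Retnlg fell by 7.13 at passage 4.

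Knockout of miR-126 was set against AE9a over the 4 passages likewise. Genes of the stefin A cluster, cysteine protease inhibitors of neutrophils and their precursors, were among the deepest falls, with Stfa3 at -4.50 ± 0.47 (22.6-fold, n = 12 and 12, adjusted p = 1.72e-07), Cstdc4 at -4.50 ± 0.45, Stfa1 at -4.25 ± 0.39 and Stfa2 at -3.91 ± 0.42. These genes are near copies of each other, and their probe sets may not tell them apart. Olfm4, a granule protein of a subset of neutrophils, fell by 4.32 ± 0.41. Among the genes that rose furthest were Car1 at 3.16 ± 0.35 (8.94-fold, adjusted p = 3.59e-07), Car2 at 2.22 ± 0.40, Rhag at 2.10 ± 0.35 and Ms4a2, a subunit of the IgE receptor, at 2.16 ± 0.33. Runx1t1 (-0.20), Runx1 (0.14), Errfi1 (-0.43), Spred1 (0.44) and Zzef1 (-0.03) did not pass. In all 1812 genes passed, 639 higher and 1173 lower, which is 8.17% of those tested, and 394 reached 2-fold. The total was 26 with passage as the unit and 1180 without passage 3. It was 2934 from the compared groups alone, 5941 with array weights and 2961 with the spread of the arrays as a covariate, where 1476 were higher and 1485 lower.

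Neutrophil and erythroid genes moved in opposite directions in the knockout. Of 25 mature neutrophil genes 22 fell (24 adjusted over the list alone, median -1.62), with Ceacam10 at -3.47 and Cxcr2, the receptor that guides neutrophils out of marrow, at -2.36. The list gave adjusted p = 1.26e-32, and adjusted p = 0.0300 with estimated correlation. Of 18 erythroid genes 13 rose (16 adjusted over the list alone, median 0.97), among them Ermap (1.94) and Klf1 (1.03), the erythroid transcription factor. The list gave adjusted p = 1.59e-19, and adjusted p = 0.0300 with estimated correlation. Cd3g (-1.58) and Thy1 (-0.80) were among 12 of 20 T and NK cell genes that fell (13 adjusted over the list alone, adjusted p = 0.0402 with estimated correlation). ERK feedback genes had 2 of 15 lower (4 adjusted over the list alone, Phlda1 -1.21, Lif -0.47, adjusted p = 0.0300 with estimated correlation). Primary granule genes had 7 of 14 lower (10 adjusted over the list alone, Ctsg -1.52, Mpo, the myeloperoxidase gene, -1.35), at adjusted p = 4.01e-09 and adjusted p = 0.063 with estimated correlation. Interferon genes had 9 of 26 higher (13 adjusted over the list alone, Mx2 1.16, Mx1 1.09), at adjusted p = 4.34e-11 and adjusted p = 0.136 with estimated correlation; 3 fell at passage 2.

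The reported miR-126 targets did not pass as a list in the knockout. Of 17 genes 0 passed in limma (1 higher and 5 lower at an unadjusted p under 0.05), with Crk at -0.35 and Vcam1 at -0.44, median -0.03 and adjusted p = 0.369. Cell cycle genes (0 of 30 passed, 2 higher unadjusted) and MYC and ribosome biogenesis genes (0 of 22, 3 higher unadjusted), each with a median of 0.16, had list adjusted p = 0.0387 and 0.014, which became adjusted p = 0.682 and adjusted p = 0.629 with estimated correlation. Monocyte and macrophage genes had 5 of 24 higher and 3 lower (6 and 5 adjusted over the list alone, Cx3cr1 1.23, Cd14 -1.03, adjusted p = 0.0737). Stem and progenitor genes had 2 of 28 higher and 4 lower (3 and 5 adjusted over the list alone, Sox4 -1.98, adjusted p = 0.598), mast cell genes 3 of 15 higher and 4 lower (4 and 4 adjusted over the list alone, Tpsb2, a tryptase, 1.59, Mcpt8 -1.45, median -0.21, mean 0.07, adjusted p = 0.524). B cell genes (1 of 18 lower, Cd79a -0.89, adjusted p = 0.0504), megakaryocyte genes (3 of 14 lower and 1 higher, 5 and 2 adjusted over the list alone, Thbs1 -1.89, adjusted p = 0.176), MHC class II and dendritic genes (0 of 15, 1 higher unadjusted, adjusted p = 0.178) did not pass as lists. Neither did stroma and endothelium genes (2 of 18 lower, Col1a1 -0.53, median 0.01, mean -0.05, adjusted p = 0.524). Immediate early genes (3 of 23 lower, 4 adjusted over the list alone, Egr3 -1.59, adjusted p = 0.0819), p53 targets (5 of 16 lower and 2 higher, 5 and 3 adjusted over the list alone, Perp -1.85, adjusted p = 0.0877) and t(8;21) markers (1 of 11 lower, Jup -1.24, median 0.01, mean -0.09, adjusted p = 0.524) did not either. The last lists that did not pass were fusion and runt genes (1 of 6 higher, 2 adjusted over the list alone, where 1 fell, Cbfa2t3 1.05, adjusted p = 0.327), sex-linked genes (0 of 4, 1 higher unadjusted, adjusted p = 0.369) and housekeeping genes (0 of 9, 1 higher unadjusted, adjusted p = 0.432).

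The knockout went with 463 genes at passage 1 (332 higher, 131 lower), 886 at passage 2 (261 and 625), 233 at passage 3 (89 and 144) and 296 at passage 4 (68 and 228). Fitted on the compared groups alone the counts were 1399, 44, 154 and 408. At passage 1 interferon genes rose, 19 of 26 (24 adjusted over the list alone), with Usp18 at 3.86, Oas2 at 3.55, Mx1 at 3.17 and Mx2 at 3.15 (adjusted p = 1.46e-44, and adjusted p = 0.00241 with estimated correlation). Oas1g, an interferon-induced gene outside the list, rose by 5.06 ± 0.62 and BC018473 by 5.13 ± 0.68. Monocyte and macrophage genes also rose there, 5 of 24 (8 adjusted over the list alone, where 1 fell), with Fcgr1 at 3.99 and Ccr2 at 2.16 (adjusted p = 0.134 with estimated correlation). At passage 2 both lists went the other way. Of 26 interferon genes 3 fell there (6 adjusted over the list alone), Oas3 at -1.74, Zbp1 at -1.68 and Oasl2 at -2.31 (list adjusted p = 0.0122, and adjusted p = 0.604 with estimated correlation). Of 24 monocyte and macrophage genes 5 fell by both adjustments, among them Fcgr1 at -1.82, Clec7a at -1.70, Lyz1 at -2.36 and Cd14 at -1.94 (list adjusted p = 0.00836, and adjusted p = 0.41 with estimated correlation). Without the arrays of low spread, replicate 3 of the knockout among them, the medians at passage 2 were -0.40 and -0.20 and neither list passed (adjusted p = 0.163 and 0.236), nor did Fcgr1, Lyz1, Cd14, Zbp1 or Oasl2. At passage 3 the interferon median was 0.61, with 0 of 26 past the limma threshold (8 higher at an unadjusted p under 0.05, 2 adjusted over the list alone, list adjusted p = 2.95e-11, and adjusted p = 0.196 with estimated correlation). At passage 4 it was -0.0042 with 1 lower by both adjustments, Igtp at -2.09 (list adjusted p = 0.67). The monocyte and macrophage medians were 0.34 and 0.20 at passages 3 and 4, where Cx3cr1 rose by 1.97 and 1.54 and, at passage 4, Ly6c1 (-1.29) and Vcam1 (-1.08) fell (list adjusted p = 0.00105 and 0.823, and adjusted p = 0.355 and 0.925 with estimated correlation). Runx1t1 was lower by 0.76 ± 0.20 in the knockout at passage 1 (adjusted p = 0.0345). Spred1 rose by 1.35 ± 0.37 (adjusted p = 0.047), a call lost after cyclic loess or quantile normalization, with the trended prior or block. Cyclic loess gave 443 higher and 351 lower genes at passage 1 and 413 and 600 at passage 2. Quantile normalization gave 291 and 214 at passage 1. With the spread as a covariate the splits were 524 and 439, 473 and 511, and 165 and 274 at passages 1, 2 and 4.

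Neutrophil genes fell in the knockout at each passage, with medians of -1.86, -1.75, -1.60 and -1.25 and 5, 9, 4 and 4 of 25 genes past the threshold (23, 20, 16 and 9 adjusted over the list alone). The lists gave adjusted p = 0.134, 0.351, 0.142 and 0.143 with estimated correlation. Erythroid medians were 0.87, 0.77, 1.35 and 0.75, with 1, 1, 6 and 1 of 18 genes higher (6, 5, 11 and 9 adjusted over the list alone), and adjusted p = 0.167, 0.351, 0.0278 and 0.143 with estimated correlation. Car1 rose by 4.28 at passage 1, 4.44 ± 0.69 at passage 3 and 2.77 ± 0.69 at passage 4, and read 1.15 at passage 2 (adjusted p = 0.396). Mast cell genes rose at passage 2, 4 of 15 (6 adjusted over the list alone, Ms4a2 3.18 ± 0.65, Fcer1a 2.51, Tpsb2 2.59, adjusted p = 0.0224, and adjusted p = 0.351 with estimated correlation). At passage 4 T and NK cell genes fell, 13 of 20 (14 adjusted over the list alone), with Cd3g (5.14, against 9.41 in AE9a, where it read 6.47 at passage 3) at -4.27, Gzmb at -3.77, Cd3e at -3.19 and Prf1, the perforin gene, at -2.39 (adjusted p = 2.68e-35, and adjusted p = 0.000251 with estimated correlation). ERK feedback genes had 1 of 15 lower at passage 4, Phlda1 by 2.84-fold (3 adjusted over the list alone, adjusted p = 0.000606 with estimated correlation).

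The single-passage counts of the knockout leaned on single mice. At passage 1 they were 135 and 132 without knockout replicates 1 and 2, and 199, 216 and 233 without AE9a replicates 1 to 3. At passage 2 they were 1805 and 192 without knockout replicates 1 and 3, and 320, 376 and 547 without AE9a replicates 1 to 3. At passage 3 they were 55 and 56 without knockout replicates 2 and 3 and 83 without AE9a replicate 1. At passage 4 each of the 6 arrays moved the count, from 105 without AE9a replicate 2 to 497 without AE9a replicate 1.

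**Figure D4:**
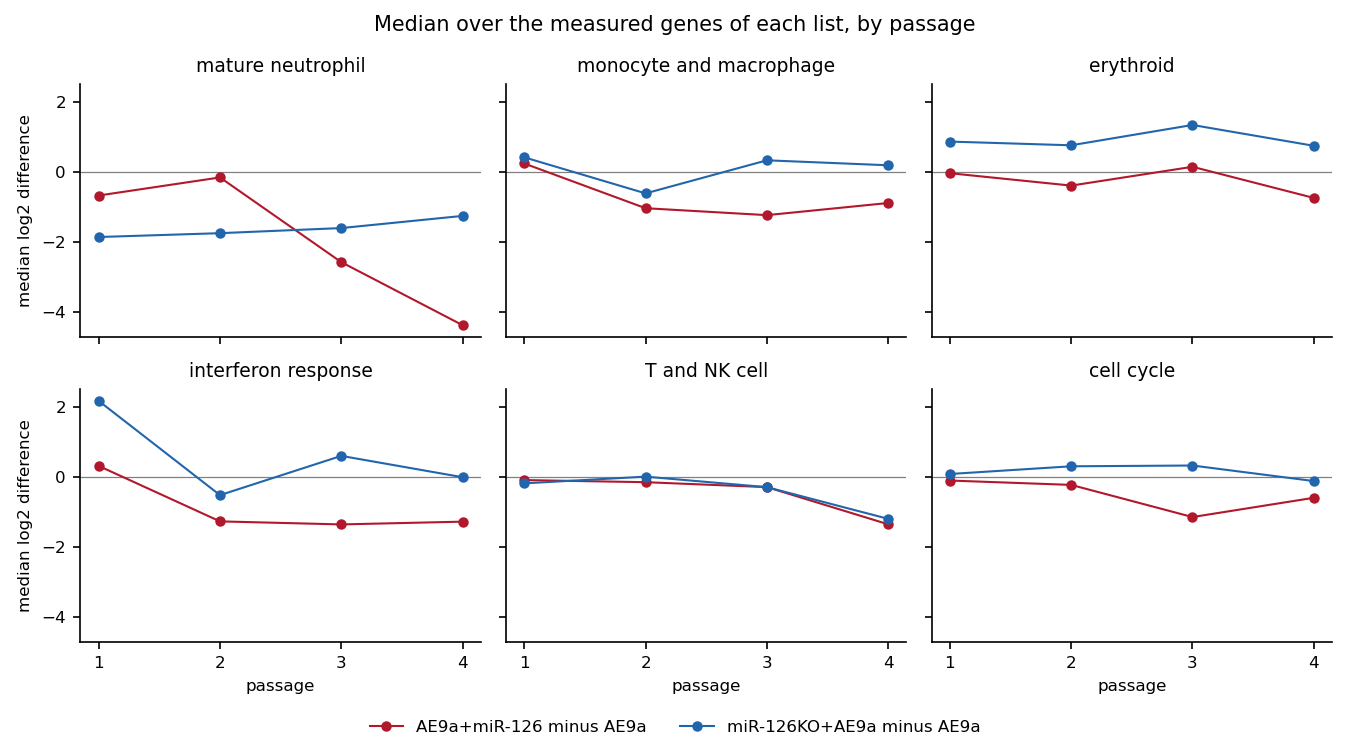
The y axis gives the median log2 difference from AE9a of the genes of 6 lists at each of 4 passages, with 1 line per miR-126 arm. Neutrophil genes reach -4.38 at passage 4 with added miR-126 and -1.86 at passage 1 in the knockout, interferon genes reach 2.18 in the knockout at passage 1, and the fall of cell cycle genes with added miR-126 turned to a rise over the 4 passages when the spread of the arrays was a covariate.

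Added miR-126 was also compared with the knockout over the 4 passages. Dscam (3.24 ± 0.27), Gria3 (3.14 ± 0.24), Cd163 (2.91 ± 0.33) and Ctsg, the cathepsin G of primary granules (2.75 ± 0.29), were higher with added miR-126. Car1 (-5.02 ± 0.35, 32.5-fold, n = 12 and 12, adjusted p = 5.69e-12), Car2 (-4.61 ± 0.40), Clec4a1 (-4.68 ± 0.26), Cd36 (-4.13 ± 0.33) and Ifi204 (-3.97 ± 0.28) were lower. Runx1t1 was higher by 0.40 ± 0.10, Runx1 (-0.65 ± 0.12), Spred1 (-1.11 ± 0.18) and Zzef1 (-0.32 ± 0.12) were lower, but Runx1 did not pass at -0.27 with the spread as a covariate or at -0.14 without all arrays of low spread, Zzef1 turned to 0.09 after cyclic loess, and Errfi1 (-0.41, adjusted p = 0.18) did not pass. In limma 11016 genes passed, 6205 higher and 4811 lower, which is 49.7% of those tested. The total was 3676 with the spread as a covariate, 2990 without passage 3, 2120 without all arrays of low spread, 7131 after cyclic loess and 267 with passage as the unit.

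Interferon genes were lower with added miR-126 than in the knockout, 23 of 26 by both adjustments (median -1.45, Usp18 -2.69, Ifitm3 -2.29, adjusted p = 1.61e-15, and adjusted p = 0.149 with estimated correlation). Erythroid genes were lower in 16 of 18 and higher in 1 by both adjustments (median -1.20, Rhag -3.36, Ermap -2.65, adjusted p = 0.19 with estimated correlation), and monocyte and macrophage genes lower in 17 of 24 and higher in 1 (18 and 1 adjusted over the list alone, Vcan -3.57, Fcgr1 -3.22, adjusted p = 0.149 with estimated correlation). MHC class II and dendritic genes (8 of 15 lower by both adjustments, H2-Aa -3.68, adjusted p = 0.196 with estimated correlation) and reported miR-126 targets (8 of 17 lower and 1 higher, 9 and 1 adjusted over the list alone, Adam9 -1.05, Ptpn9 -0.61, adjusted p = 0.23 with estimated correlation) were lower. Ptpn9 lost its call here after cyclic loess and without all arrays of low spread. Cell cycle genes were lower in 23 of 30 (25 adjusted over the list alone, Ccna2 -1.41, at -0.20 and not called without all arrays of low spread, adjusted p = 0.464 with estimated correlation), with a median of -0.66 that was -0.41 without passage 3 and turned to 0.33 without all arrays of low spread. Neutrophil genes went both ways, with 4 of 25 higher (Stfa1 2.47) and 8 lower (Itgam -1.95), and did not pass (adjusted p = 0.203).

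Across genes the averaged effects of added and deleted miR-126 against AE9a correlated at 0.357 with a covariance of 0.0575. Both are measured against the same AE9a arrays, and simulated unchanged groups against those arrays gave a mean correlation of 0.483 (from -0.577 to 0.882) and a covariance of 0.0101, which leaves 0.0474. With the AE9a arrays split into 2 sets of 6, 1 for each effect, the mean correlation over 100 splits was 0.328 (0.0604 to 0.536) and the covariance 0.0532. Neither the simulation nor the split removes what is particular to AE9a. Of 1162 genes that passed in both, 947 went the same way, 73 higher and 874 lower, against 196 and 285 for independent lists. Another 21 were higher with added and lower with deleted miR-126 (360 independent), and 194 the reverse (155 independent).

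In AE9a, passage 4 was compared with passage 1. Csta2 (55.6-fold, n = 3 and 3, adjusted p = 1.02e-05) and the chemokine genes Ccl2 (4.71 ± 0.69) and Ccl7 (4.19 ± 0.66) rose, and Plet1 (-4.76 ± 0.37) and Mreg (-4.05 ± 0.49) fell. Immediate early genes rose in 11 of 23 (16 adjusted over the list alone, median 1.70), with Egr3 at 3.03, Egr1 at 2.99, Fosb at 2.74 and Jun at 1.73 (adjusted p = 1.45e-18, and adjusted p = 0.0349 with estimated correlation). Gzmb (3.89) and Cd8a (2.51) were among 7 of 20 T and NK cell genes that rose (10 adjusted over the list alone, adjusted p = 0.0349 with estimated correlation). Monocyte and macrophage genes rose in 6 of 24 (9 adjusted over the list alone), with C1qb, a complement gene of macrophages, at 3.93 (adjusted p = 0.0349 with estimated correlation). ERK feedback genes rose in 2 of 15 (7 adjusted over the list alone, Etv5 0.93, adjusted p = 0.0189 with estimated correlation). B cell genes fell in 2 of 18 (11 adjusted over the list alone, Ebf1 -1.60, adjusted p = 0.0813 with estimated correlation). MYC and ribosome biogenesis genes, Myc among them, rose in 2 of 22 (12 adjusted over the list alone, adjusted p = 0.15 with estimated correlation). There were 652 genes past the threshold, 449 higher and 203 lower. The split was 741 and 562 after cyclic loess, 410 and 343 after quantile normalization, 919 and 566 from the compared groups alone, and 693 and 799 with the spread as a covariate. Without replicates 1 to 3 of passage 1 the totals were 297, 344 and 436, and without those of passage 4 421, 383 and 372.

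With added miR-126, passage 4 against passage 1 gave 5395 genes, 2469 higher and 2926 lower, but 1961 higher and 1440 lower with the spread as a covariate, and 209 and 1350 from the compared groups alone. Tmem178 (5.48 ± 0.53, 44.7-fold), Clec2m (3.99 ± 0.38) and Stag3, a cohesin subunit known from meiosis (3.96 ± 0.51), rose, and Il1a (-6.64 ± 0.83, 99.8-fold), Retnlg (-6.57 ± 0.62) and Acod1 (-5.95 ± 0.83) fell. Neutrophil genes fell in 23 of 25 by both adjustments (Ngp -3.66, S100a8 -4.62, adjusted p = 1.97e-23, and adjusted p = 0.197 with estimated correlation). MYC and ribosome biogenesis genes rose in 9 of 22 (12 adjusted over the list alone, where 1 fell), with Myc at 2.32 and Ppan at 1.95 (adjusted p = 0.658 with estimated correlation). Reported miR-126 targets fell in 8 of 17 and rose in 1 (8 and 2 adjusted over the list alone), with Errfi1 at -2.40 ± 0.52 and Spred1 at -1.85 ± 0.37 (adjusted p = 0.437 with estimated correlation). Egfl7 rose by 0.58 ± 0.21. The probe set of Mir126a and Egfl7 was at -1.03 (adjusted p = 0.132). Low-spread arrays were among passage 4 and not passage 1, and the median over all genes of 0.127 became 0.002 after cyclic loess. The total was 2717, 2779 and 9796 without replicates 2, 1 and 3 of passage 4, and 3015 and 3363 without replicates 1 and 3 of passage 1.

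In the knockout, passage 4 against passage 1 gave 897 genes, 307 higher and 590 lower (810 and 925 with the spread as a covariate, 703 and 1068 from the compared groups alone). Zbtb16, the transcription factor PLZF (4.25 ± 0.53, 19-fold), and Ace, angiotensin-converting enzyme (4.18 ± 0.50), rose, and Mmp13 (-5.37 ± 0.72), Pgf (-4.71 ± 0.61) and Il7r, the interleukin 7 receptor (-4.70 ± 0.77), fell. Interferon genes fell in 11 of 26 (19 adjusted over the list alone), with Ifit1 at -4.24 and Cxcl10 at -3.29 (adjusted p = 2.41e-20, and adjusted p = 0.0561 with estimated correlation). Immediate early genes rose in 8 of 23 (11 adjusted over the list alone, Fos 3.56, Nr4a1 3.12, adjusted p = 0.24 with estimated correlation). Erythroid genes rose in 1 of 18, Rhd by 1.58 (7 adjusted over the list alone, adjusted p = 0.24 with estimated correlation), and Egfl7 rose by 0.80 ± 0.21. Leaving out replicates 2 and 1 of passage 1 gave 531 and 547 genes.

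Whether the effect of miR-126 differed between passages 4 and 1 was tested as a difference of differences. For added miR-126 it did in 2336 genes, 1018 with a higher and 1318 with a lower effect at passage 4 (208 and 1142 from the compared groups alone). Tmem178 (5.70 ± 0.74), Clec2m (4.21 ± 0.54) and Mid1 (3.55 ± 0.58) had higher effects, and Stfa3 (-6.56 ± 1.33), Retnlg (-6.48 ± 0.88, 89.2-fold, adjusted p = 1.96e-05) and Ifi204 (-6.46 ± 0.78) lower ones. Neutrophil genes had a lower effect in 19 of 25 (20 adjusted over the list alone, Ngp -3.47) and monocyte and macrophage genes in 8 of 24 (12 adjusted over the list alone, Vcan -5.38). So did T and NK cell genes in 9 of 20 with 1 higher (12 and 1 adjusted over the list alone, Ccl5 -5.32) and reported miR-126 targets in 5 of 17 (7 adjusted over the list alone, Errfi1 -2.45, Spred1 -1.91). Each of these 4 lists passed, with adjusted p = 6.03e-18, 2.94e-08, 4.84e-08 and 0.00159, and each gave adjusted p = 0.0998 with estimated correlation. The median over all genes was 0.102 and became -0.018 after cyclic loess. The total was 818 without AE9a replicate 1 of passage 1 and 1225 and 1368 without AE9a replicates 1 and 3 of passage 4. With added miR-126 it was 1156 and 1196 without replicates 1 and 3 of passage 1, and 918, 896 and 8452 without replicates 1, 2 and 3 of passage 4.

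For the knockout the effect differed between passages in 95 genes, 11 with a higher and 84 with a lower effect at passage 4 (57 and 114 with the spread as a covariate, 91 and 333 from the compared groups alone). Adgrl4 (3.28 ± 0.74) and Mreg (3.18 ± 0.70) had higher effects, and Csta2 (-6.31 ± 0.99, 79.1-fold, adjusted p = 0.00174), Tph1, the serotonin synthesis enzyme of mast cells (-5.73 ± 0.94), and BC018473 (-5.25 ± 0.97) lower ones. Interferon genes had a lower effect at passage 4 in 10 of 26 (22 adjusted over the list alone, median -2.25, Igtp -4.32, Zbp1 -3.20, adjusted p = 6.17e-36, and adjusted p = 0.0072 with estimated correlation). Gzmb (-3.86), Cd3g (-3.54) and Prf1 (-2.56) were among 7 of 20 T and NK cell genes that did (10 adjusted over the list alone, adjusted p = 0.00972 with estimated correlation). ERK feedback genes had 0 of 15 past the limma threshold and 3 lower at an unadjusted p under 0.05 (Spry2 -1.21), with list adjusted p = 1.02e-05 and adjusted p = 0.0072 with estimated correlation. Without AE9a replicates 1 and 2 of passage 1 the total was 55 and 51, and without those of the knockout 58 and 42. Without AE9a replicates 1 to 3 of passage 4 it was 147, 48 and 43, and without knockout replicates 1 and 2 there 57 and 49.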

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

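The tests with the spread as a covariate, with quantile normalization, without the arrays of low spread, in arrays of normal spread and over lists of mature cell types were chosen after the result was seen, while the splits of arrays were written down before theirs. The effect of added miR-126 differed between passages 4 and 1 in 2336 genes, and that of the knockout in 95. Both were singled out because a test of the difference itself called genes. Retnlg (-6.48 ± 0.88) had a lower effect of added miR-126 at passage 4, and Igtp (-4.32) a lower effect of the knockout. Of 100 splits 2 gave as many genes for each, the real one included, and the highest other splits gave 2869 and 373 genes. The split with 373 exchanged 2 arrays of each arm at passage 4 and 0 at passage 1, and that with 2869 did the reverse. The splits exchange arms within a passage, so they test for any arm effect. They cannot decide whether it differed between passages.

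In the averages over passages 1 of 100 splits, the real one, gave as many genes, which excludes a random partition of the arrays. The real and highest other counts were 12211 and 3199 for added miR-126 against AE9a, 1812 and 498 for the knockout against AE9a, and 11016 and 9942 for added miR-126 against the knockout. For 3 mice against 3 the 10 splits are too few for a share under 0.05. The real and highest other counts were 1967 and 3 for AE9a, 2159 and 1 for added miR-126 and 2393 and 0 for the knockout, each against normal controls. Against AE9a at passages 1 to 4 they were 7 and 2, 1964 and 12, 11567 and 1, and 5488 and 4106 for added miR-126, and 463 and 0, 886 and 0, 233 and 58, and 296 and 6 for the knockout. For passage 4 against passage 1 they were 652 and 1 in AE9a, 5395 and 3548 with added miR-126 and 897 and 1 in the knockout.

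In all 12211 genes differed between added miR-126 and AE9a, and 7 of 8 arrays of low spread lie in this arm. Of the 10909 genes passing at under 2-fold, 961 (8.81%) passed in the same direction with the spread as a covariate. After quantile normalization, which equalizes spread, 5566 did, and 4312 after cyclic loess. Across genes the difference fell with mean level (r = -0.559, knockout -0.162), as compression would give. Its share stays open, since spread is tied to the arm and the covariate costs power. The 1302 genes at 2-fold or more argue against compression as the whole cause. In the same direction 868 (66.7%) passed with the covariate, 1297 after quantile normalization and 1286 after cyclic loess. Without the arrays of low spread, over passages 1, 2 and 4, 463 did. The 2 arrays of normal spread at passages 2 and 4, both replicate 3, were left out to choose 1951 genes at 2-fold or more. On these genes they had a median of 0.311 (quartiles 0.108 and 0.640) of the low-spread difference. Fewer normal donor cells would lower markers of mature cells that the leukaemia lacks. Among 7 such lists the highest lower quartile was -0.315. Upper quartiles exceeded 0 for MHC class II (0.14), B cell (0.11) and mast cell genes (0.23). Neutrophil genes did not pass between AE9a and normal marrow (median -0.09). The Mir126a probe set read 8.18 to 8.48 at passage 1 (7 genes) and 5.90 to 7.46 at passage 3 (11567). Replicate 3, with the weaker pattern, read highest at passages 2 and 4 (11.6 and 8.59). Compression would lower high values and raise counts, so this cannot test miR-126 dose. How much comes from compression, cell composition, donor clones that differ between the arms or miR-126, the explanation the design names, stays open. Y-linked Eif2s3y read at most 4.33 with added miR-126 at passages 2 to 4 and 3.59 to 8.30 in AE9a.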

How the results depend on the processing

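Quantile normalization, spread as a covariate and leaving out arrays of low spread were chosen after the data were seen. Of the counts recomputed under another setting 239 stayed within 1.5 times and 164 did not, 68 of the latter from leaving out 1 array. Of the list results 928 kept direction and call, 340 kept direction and lost the call, 154 of those with estimated correlation, and 19 turned. Of the values of named genes 2525 kept direction and call, 141 lost and 18 gained the call, and 14 turned. The correlation between the 2 miR-126 effects kept its sign in 11 settings, from 0.166 without arrays of low spread to 0.460 without passage 1. The cause was not tested except where the setting itself shows it: a fold minimum, a filter and fewer arrays leave fewer genes or arrays. Signal near the floor limits microRNA genes, and the knockout of miR-126 cannot be seen for that reason. Without arrays of low spread added miR-126 could not be compared at passage 3, so its averages then run over passages 1, 2 and 4.

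With the replicate number as a replicate block the averages gave 12012, 1757 and 10735 genes for added miR-126, the knockout and their difference, and 0 counts moved by more than 1.5 times and 0 lists changed their call. Of the values of named genes 6 passed without the block and not with it, Runx1 with added miR-126 against normal controls, Spred1 in the knockout at passage 1, Ly6c1 and Vcam1 in the knockout at passage 4, and Etv5 in AE9a and Egfl7 with added miR-126 for passage 4 against 1. Same-numbered arrays deviated together in every pair in 1 of 19 comparisons, so the numbers were not taken as pairs.

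Counts below run in the order AE9a, added miR-126 and knockout for passage 1 against normal controls, then added, knockout and added against knockout for the averages. A 2-fold minimum gave 1089, 1223 and 1473, then 1302, 394 and 1087, and for added miR-126 1013, 5089 and 2370 at passages 2 to 4 and 2600 for passage 4 against 1. Array weights gave 6954, 8273 and 6099, and 5941 for the knockout average. They gave 2557, 10569 and 15278 for added miR-126 at passages 1, 2 and 4, 3459, 4161, 2258 and 2453 for the knockout at passages 1 to 4, 3691, 16509 and 3634 for passage 4 against 1, and 13981 and 1731 for the changes of the 2 effects. Cyclic loess gave 3021 for AE9a against normal controls, 7872 and 7131 for the averages with added miR-126, 1097 and 6767 for added miR-126 at passages 2 and 3, 794 and 363 for the knockout at passages 1 and 3, 1303 and 1530 for passage 4 against 1 in AE9a and the knockout, and 1154 for the change of the effect of added miR-126. Quantile normalization gave 994 for added miR-126 at passage 2 and 1180 for the change of its effect.

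With the spread as a covariate the counts were 3622, 4043 and 4232, then 2813, 2961 and 3676. They were 535, 1744 and 2319 for added miR-126 at passages 2 to 4, 963 and 471 for the knockout at passages 1 and 3, 1492, 3401 and 1735 for passage 4 against 1, and 751 and 171 for the changes of effect. Without arrays of low spread they were 4533, 3999 and 4189, then 982 for added miR-126 and 2120 against the knockout. They were 506 and 2117 for added miR-126 at passages 2 and 4, 1223, 501, 489 and 618 for the knockout at passages 1 to 4, 1875, 3073 and 1886 for passage 4 against 1, and 975 and 235 for the changes of effect. A filter on dim genes gave 6432 and 5984 for the averages with added miR-126, 4, 6463 and 3263 for it at passages 1, 3 and 4, and 1556 for the change of its effect. Without passage 3 the averages gave 4204, 1180 and 2990, and with passage as the unit 1, 26 and 267. Groups compared alone gave 2934 for the knockout average, 2, 917, 7261 and 1357 for added miR-126 and 1399, 44 and 154 for the knockout by passage, 1485, 1559 and 1771 for passage 4 against 1, and 1350 and 424 for the changes of effect. All probe sets gave 423 for the knockout at passage 3.

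Leaving out 1 array at a time gave 865 to 1776, 1319 to 1653 and 1518 to 1959 genes against normal controls, and 10800 to 14099, 1464 to 2047 and 9409 to 13403 for the averages. It gave 3 to 57, 396 to 4694, 7270 to 11923 and 2126 to 10765 for added miR-126 at passages 1 to 4, and 132 to 547, 192 to 1805, 55 to 323 and 105 to 497 for the knockout. For passage 4 against 1 the ranges were 297 to 436, 2717 to 9796 and 531 to 775, and for the changes of effect 818 to 8452 and 42 to 147.

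Cell cycle genes turned in the average of added miR-126 with the spread as a covariate (median 0.19) and without arrays of low spread (0.37), and against the knockout without those arrays (0.33). With the covariate they turned at passages 3 (0.334) and 4 (0.351) of added miR-126, and at passage 4 also without arrays of low spread (0.533). In the change of the effect of added miR-126 they turned with a dim filter by the test while the median was -0.44, after cyclic loess (0.12) and quantile normalization (0.0463), with the covariate (0.65) and without arrays of low spread (0.67). Immediate early genes turned by the test after cyclic loess in the average of added miR-126 (median -0.00108). At its passage 2 they turned without arrays of low spread (0.251), and at its passage 3 by the test with a dim filter (median -0.416) and after cyclic loess (0.566), where housekeeping genes turned too (0.581, and 0.0352 with the covariate). Against the knockout sex-linked genes turned by the test with a dim filter (median -0.59) and housekeeping genes after cyclic loess (0.17). Among named genes in the average of added miR-126, without arrays of low spread Ccna2 turned to 0.27, Hprt to 0.134, Rrm2 to 0.353, Runx1 to 0.0479 and Spred2 to 0.114, and after cyclic loess Ptprc turned to 0.00763. Zzef1 turned in that average after cyclic loess (0.110) and quantile normalization (0.0563) and with the covariate (0.142) and without arrays of low spread (0.122), and against the knockout in the same settings (0.0859, 0.00227, 0.0814 and 0.157). In at least 1 of these 4 settings other named genes lost their call, among them Gria3, Il1r2, Mki67 and Dusp5 with added miR-126 at passages 2 to 4, Mt2 and Selp at its passage 1, Ms4a2 and Fcer1a at passage 2 and Igtp at passage 4 of the knockout, Egfl7 for passage 4 against 1, and Errfi1 and Spred1 in the change of the effect of added miR-126.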

Other observations

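The tests of passage 1 slopes, cell share and normalization below were chosen after their patterns were seen on the same arrays. With added miR-126 B cell genes split between passages 4 and 1, with 3 of 18 higher (Igll1 2.38, Dntt 2.25) and 7 lower (Cd79a -2.50), 3 and 8 adjusted over the list alone (adjusted p = 0.0908).

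Sex-linked genes differed: Y-linked Eif2s3y read below 5 in 19 arrays, where Xist, the RNA of the inactive X chromosome, read 11.2 to 12.1. In 15 arrays Eif2s3y read 7 or more with Xist at 10 or more, and in 2 Xist read below 8 with Eif2s3y at 8.68 to 9.29. With added miR-126 Eif2s3y read 6.90 to 7.26 in replicates 1 and 3 of passage 1 and 4.19 in replicate 2. In the knockout it was at most 4.02 at passage 2 and at least 8.04 at passages 3 and 4. In the knockout at passage 3 Eif2s3y (4.05 ± 0.86), Uty (3.54) and Kdm5d (3.44) were higher than in AE9a, 3 of 4 listed genes by both adjustments (adjusted p = 2.02e-07, and adjusted p = 0.00136 with estimated correlation).

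In the knockout neutrophil genes were lower (median -1.62) and erythroid genes higher (median 0.97) than in AE9a. At passage 1 neutrophil genes lay below both AE9a and normal marrow (upper quartiles at most -0.897), which more normal cells alone could not give. Such cells would raise erythroid and B cell genes alike, both lower in AE9a than in normal marrow. Yet the erythroid lower quartile lay 0.498 above the B cell upper quartile. Later passages have no normal controls of their own. List medians kept at least 0.961 of their size under cyclic loess, quantile normalization and spread as a covariate, arguing against normalization and unequal spread. A shift of the leukaemia or normal donor cells from neutrophil toward erythroid genes without miR-126 could be behind it. Neutrophil genes also fell with added miR-126 (median -1.92), so their fall need not follow from its loss. It was found and tested on the same arrays, and donor clones that differ between arms stay open.

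Added miR-126 went with 564 genes that differed by 2-fold or more from AE9a at each of passages 2, 3 and 4, 143 higher and 421 lower. If cells with that pattern had been present at passage 1 and grew out, passage 1 arrays could carry a diluted form of it, and the highest slope of such an array with added miR-126 on the later pattern was 0.110 for the rising genes and -0.0272 for the falling genes, within the AE9a arrays (-0.152 to 0.226 and -0.111 to 0.0569), so a small share is neither seen nor excluded. A later array labelled as passage 1 was tested with each later array held out of the choice of genes, and the smallest excess over the highest passage 1 slope on the same genes was 0.205 (0.318 for replicate 3 of passage 2 against 0.113), less than the range of the AE9a arrays there (-0.130 to 0.130), so it stays open for an array like that one. With added miR-126, replicate 2 of passage 1 read Cd163 at 9.11, Dscam at 8.15 and H2-Ab1 at 5.65, against 4.88, 5.58 and 9.77 in replicate 1 and 7.89, 7.24 and 9.39 in replicate 3. Its Y-linked genes were lower too, with Kdm5d at 3.33 against 5.22 and 4.31 in replicates 1 and 3, but 0.110 and -0.0272 are its own slopes, and over all 564 genes, chosen from the later arrays, its slope was -0.000415 against 0.588 to 1.20 in those.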
